A study of Caulobacter vibrioides CB15 with 23 samples.

How the data were processed

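Hi-C was measured in 17 libraries of Caulobacter crescentus and genomic DNA in 6. Per the submitters' processing notes, reads were handled with Bowtie2 2.1.0; the genome build and filters are not given in the sources used here. For each Hi-C library the authors deposited a map before and after normalization. The BglII maps before normalization were deposited by the authors as estimated counts of contacts that need not be whole, and the NcoI map before normalization was deposited as whole counts. The maps after normalization were deposited as fractions of each bin's contacts, with pairs 0 and 10 kb apart set to 0. The genomic DNA files were deposited by the authors as RPM, read depth scaled to the library total, in 4043 windows, taken as 1 kb. Samples were grouped by titles and characteristics. The labels give differing lists of times, and those of the titles (0, 10, 30, 45, 60 and 75 min) were used.

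The deposited normalized maps were used for all main values. They were compared with iterative balancing of the maps before normalization (200 iterations, pairs up to 10 kb apart left out), and over 98% of cells came within 0.0001 in every library, with correlations of at least 0.998. Because pairs at 10 kb are 0 in these maps, the planned share at 10 kb was not computed, and leaving them out is the setting used throughout; balancing with 10 kb pairs kept was added. The directional preference score of a bin compared log2 contacts (pseudocount 1e-04) to its right and left at the 9 distances from 20 to 100 kb. A boundary lay between consecutive bins past a two-sided limit of 0.05 that went from left to right preference, at most 100 kb apart, at the lowest insulation score between them. The insulation score was log2 of the mean contact between the 50 kb on each side of a bin over the median bin. Boundary depth was the mean score 50 to 80 kb to each side minus the lowest score within 10 kb. Inter-arm contacts were summed within 50 kb of mirrored positions at least 400 kb apart and divided by the sum of the mean at the same distance. Calls were tested on simulated data: with 24 boundaries that kept 0.8 of contacts, 98.3% were recovered at the depth of the deepest library and 92.5% at that of the shallowest, and with no boundary 2.0 and 1.8 were called on average among 405 bins.

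Contacts per library ranged from 1167812 to 12850294. Counting SDs came from 50 Poisson draws of each map before normalization, balanced again, and cover counting error only. Boundary sets were compared by all 405 circular shifts, drug effects by 10000 random sets of bins, and times by all 720 orders (two-sided), with Benjamini-Hochberg adjustment. Nothing says that the 2 replicates came from separate cultures, so their SD may be technical. No test between conditions was made for groups of 1 library, and the overlap of boundaries and the random sets of bins compare libraries or positions within them. The design, groups and alternatives were fixed before the data were examined, except those named as added. Alternatives were own balancing, thinning to the shallowest library, other windows, limits, tolerances, bands, axes and references, leaving out each replicate, and other summaries of read depth.

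The rule for named genes took target genes and listed genes in boundary bins. The sample titles name strain NA1000, while the gene table at hand is of assembly ASM690v1, of strain CB15, and the maps name no build. So no gene was placed, the planned test of gene lists at boundaries was not run, and bins at van and xyl were taken from the maps. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.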

Results

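Caulobacter crescentus is an alphaproteobacterium with 1 circular chromosome, and its non-replicating swarmer cells can be isolated by density, which gives a synchronous population. Hi-C, in which crosslinked DNA is cut, ligated and sequenced so that ligated pairs count contacts, was performed in 17 libraries, and genomic DNA was sequenced in 6 libraries of a time course. Untreated wild-type swarmer cells cut with BglII were the only group with 2 replicates, and every other group was 1 library. The 2 replicates held 7153164 and 8237605 contacts, the wild-type library cut with NcoI held 12850294, and the shallowest library, novobiocin at 50 µg/ml, held 1167812. The sample titles name strain NA1000. Map bins were taken as 10 kb each, and positions are given on the map of the files, whose genome build was not given in the sources used here. No gene was placed on this map.

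The wild-type maps were first read for domain boundaries, positions across which neighbouring DNA made few contacts. The mean map of the 2 replicates had 27 boundaries with a median spacing of 140 kb. The deepest lay in the bin from 1430001 to 1440000, where the insulation score (log2 of the contacts across a bin relative to the median bin) was -0.87 in replicate 1 and -1.07 in replicate 2. Next by boundary depth (0.83 and 0.61) were 2 bins. They ran from 1170001 to 1180000 (scores -0.68 and -0.94, but -0.45 in the untreated 0 min library of the time course) and from 550001 to 560000 (-0.43 and -0.58). The bin from 3260001 to 3270000 had lower scores than the last (-0.51 and -0.67) but a depth of 0.49. The boundary from 3790001 to 3800000 had a call within 10 kb in all 17 libraries, and those from 1430001, 2860001 and 3260001 in 15. Those centred on 1.715, 2.665 and 0.255 Mb had such a call in only 1, 2 and 3 libraries. Not every boundary called had few contacts across it. Scores in the mean map were above the median bin at 1.635, 1.715, 1.805 and 1.945 Mb (0.06, 0.24, 0.32 and 0.06). Boundary depth was negative at 1.715 and 1.805 Mb (-0.02 and -0.05). All 27 were kept in the comparisons below. Replicate 1 had 26 boundaries, of which 24 (92.3%) lay within 10 kb of one of the 28 in replicate 2, against a mean of 20.7% over all circular shifts (one-sided permutation over shifts, p = 0.00247, the smallest they can give; Benjamini-Hochberg adjusted p = 0.00658 over all pairs of the 17 libraries). Of the boundaries of replicate 1, 17 (65.4%) were shared with the NcoI library (permutation p = 0.00247, adjusted p = 0.00658). A shift treats positions as exchangeable, and the test says nothing on how cells of other cultures vary.

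**Figure D1:**
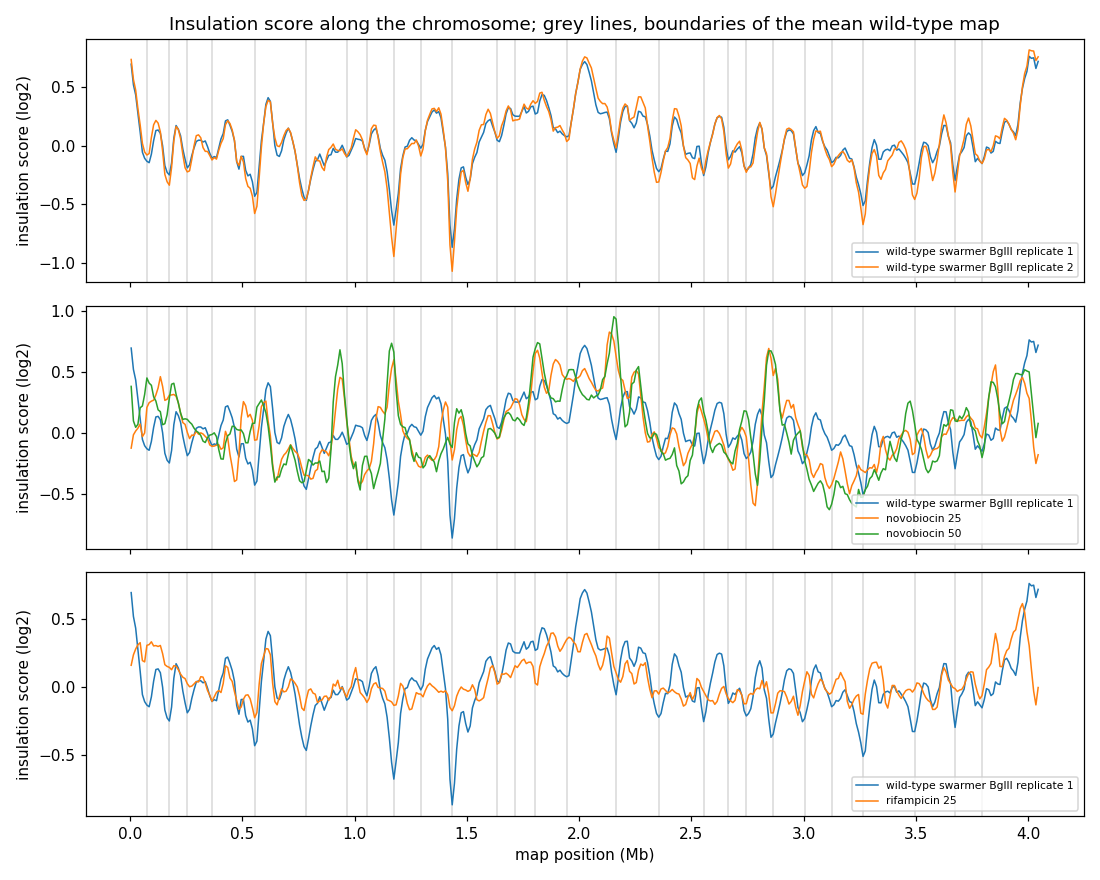
Insulation score (log2) against map position (Mb) for both wild-type replicates, the novobiocin libraries with replicate 1, and rifampicin with replicate 1, with boundaries of the mean wild-type map as grey lines. At the boundary centred on 1.175 Mb the score was -0.68 in replicate 1, 0.60 and 0.66 with novobiocin at 25 and 50 µg/ml, and -0.13 with rifampicin.

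Contacts in wild-type swarmer cells declined with distance and were enriched between the chromosome arms. Pairs 20 to 200 kb apart made up 46.1% ± 2.01 (SD, n = 2) of contacts, and the slope of log contact on log distance was -0.936 ± 0.0318 (SD, n = 2). Positions mirrored about coordinate 0 on the opposite arms made 2.98 ± 0.106 times (SD, n = 2) the mean contacts of all pairs at the same distance. The ratio was 3.38 ± 0.153 (SD, n = 2) in the origin-proximal part of the map and 2.57 ± 0.0582 in the terminus-proximal part. The NcoI library gave 46.6% and an inter-arm ratio of 3.38. The axis of highest inter-arm contacts was shifted from coordinate 0 by -45 and -65 kb in the replicates (ratios 3.07 and 3.52). In the NcoI library the shift was -20 kb (3.43), and with rifampicin it was -15 kb. The origin-proximal and terminus-proximal parts were not measured on the shifted axis. Differences in them between libraries may thus include an offset of the axis, which was not tested. The replicates differed by more than their counting error, since their shares of 44.7% and 47.5% each had a counting SD under 0.04. The 0 min library of the time course, a further untreated library, gave 43.2% and 2.74.

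Novobiocin, an inhibitor of DNA gyrase, and rifampicin, an inhibitor of RNA polymerase, were each given for 30 min to ask how supercoiling and transcription bear on domain boundaries. With novobiocin the 27 wild-type boundaries were shallower: the median difference in depth was -0.26 at 25 µg/ml and -0.37 at 50 µg/ml, and 23 of the 27 were shallower at each dose. The bin from 1170001 to 1180000, a deep boundary in wild-type cells, had more contacts across it than the median bin (0.60 and 0.66, against a wild-type mean of -0.81), as did the bin from 2860001 to 2870000 (0.47 and 0.63, against -0.43). Rifampicin gave a median difference of -0.25, with 23 of 27 shallower, and the 2 deepest boundaries were at -0.17 and -0.13 in place of -0.97 and -0.81. At the second of these the replicates stood apart from the other BglII libraries. Rifampicin differed less there from the untreated 0 min (-0.45) and 30 min (-0.31) libraries, the empty-plasmid strain (-0.25) and rsaA at xyl (-0.16). Beside the origin, in the bin from 4030001 to 4040000, scores were -0.25, -0.04 and -0.13 for novobiocin 25, novobiocin 50 and rifampicin, against a replicate mean of 0.69. Without drug, that bin was at 0.51, -0.04 and 0.43 in the 0, 10 and 30 min libraries and at 0.31 in the smc knock-out. Among 10000 random sets of 27 bins, the median differences fell at percentiles 0.07, 0 and 0 for these libraries and at 18.4 for the untreated 0 min library, whose difference was -0.02. The 27 bins were called in the replicates that also serve as reference, so they lean to shallower in any library whose profile differs. The percentiles and counts of shallower boundaries cannot separate a drug effect from this choice of bins. At boundaries called in the 0 min library (added), the median differences were -0.31, -0.37 and -0.24 for novobiocin 25, novobiocin 50 and rifampicin. With 1 library per drug there was no test between conditions, and differences are set beside an SD of 0.0337 over the 3 untreated libraries. These were the 2 replicates and the 0 min library, with median depths of 0.28, 0.34 and 0.28. The 30 min library (0.21) and the NcoI library (0.28) were left out of this SD. Against the 30 min library of the time course, which matches the length of incubation, the differences were -0.16 for rifampicin and -0.26 and -0.36 for novobiocin at 25 and 50 µg/ml. Genomic DNA depth at 30 min was 1.66 times as high around the origin as around the terminus, so cell-cycle stage may differ from that of the drug-treated cells. With a 100 kb insulation window the differences were -0.17 for rifampicin and -0.16 and -0.19 for novobiocin at 25 and 50 µg/ml.

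Overlap of boundary positions was compared between single libraries, not conditions. Of the 26 boundaries of replicate 1, 4 lay within 10 kb of a boundary at 25 µg/ml and 2 at 50 µg/ml, which was not above the overlap of shifted sets (permutation p = 0.662 and 0.931). In turn, 12 of the 20 boundaries at 50 µg/ml lay near one at 25 µg/ml (permutation p = 0.00247, adjusted p = 0.00658). Rifampicin shared 11 of 26 with replicate 1 (permutation p = 0.00741, adjusted p = 0.0102). Across bins, which are not independent replicates, insulation correlated at 0.307 and 0.251 between replicate 1 and novobiocin at 25 and 50 µg/ml, at 0.583 with rifampicin, and at 0.980 between replicates.

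The share at 20 to 200 kb was 32.5% and 31.6% with novobiocin at 25 and 50 µg/ml, 0.706 and 0.685 times the wild-type mean, and 40.7% with rifampicin, 0.883 times the wild-type mean but 0.942 times the untreated 30 min library. Contacts at 210 to 800 kb were 35.3%, 35.2% and 34.8% in these 3 libraries, against 28.1% and 27.6% in the replicates. Over 800 kb they were 32.1% and 33.3% with novobiocin at 25 and 50 µg/ml but 24.5% with rifampicin, below the 27.2% and 24.9% of the replicates. The SD of the ratio over the 3 untreated libraries was 0.0477. Each drug was measured once.

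**Figure D2:**
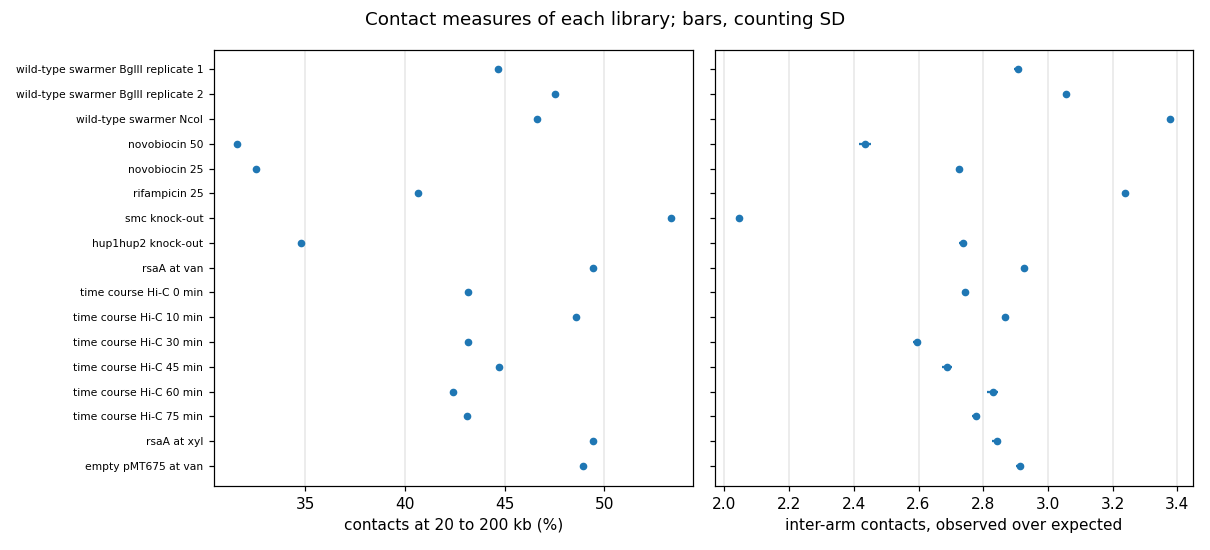
Share of contacts at 20 to 200 kb (percent, left) and inter-arm contacts (observed over expected, right) in each of the 17 Hi-C libraries, 1 point per library, with bars for the counting SD. The smc knock-out had the highest share (53.3%) and the lowest inter-arm ratio (2.05).

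The smc knock-out lacks the SMC protein, a condensin-type chromosome organiser, and the hup1hup2 knock-out lacks both subunits of the nucleoid protein HU. Without smc, inter-arm contacts were lower, at 2.05 against 2.98 ± 0.106 (SD, n = 2), or 0.686 times the wild-type mean, with 2.32 in the origin-proximal part and 1.77 in the terminus-proximal part. The terminus-proximal value was also low in rsaA at xyl (1.76), a strain not labelled as lacking smc. Contacts at 20 to 200 kb were higher, at 53.3% (1.16 times wild type), and 22 of the 27 wild-type boundaries had a boundary within 10 kb. Among libraries without drug or knock-out, this share ranged from 42.4% at 60 min to 49.4% in rsaA at xyl. Without hup1 and hup2, contacts at 20 to 200 kb were lower, at 34.8% (0.755 times wild type), with the larger part of the difference at 20 to 100 kb (20.6% against 29.8% and 32.7%). The hup1hup2 inter-arm ratio was 2.74, equal after rounding to the untreated 0 min library, and 15 of 27 boundaries had a boundary within 10 kb, against 21 and 16 in the untreated 0 and 30 min libraries. The median difference in boundary depth was -0.04 in smc cells, with 20 of 27 shallower and percentile 12.2 among random sets. It was -0.12 in hup1hup2 cells, with 21 of 27 shallower and percentile 0.44, against the SD of 0.0337 over untreated libraries. As for the drugs, the bins were called in the reference replicates, so the percentiles cannot separate a mutant effect from this choice. Median depth was 0.14 in hup1hup2 cells, against 0.30, 0.21, 0.25, 0.20 and 0.21 at 10, 30, 45, 60 and 75 min, which the SD leaves out. Alternative settings were not run for boundary depth in the mutants. The untreated 0 and 30 min libraries had 19 and 16 of 27 shallower. Each mutant was 1 library and had no test, and the SD of the inter-arm ratio relative to wild type was 0.0525 over the same 3 untreated libraries. The NcoI library, with inter-arm contacts of 3.38, was left out of it. The deleted genes could not be checked in the maps because their positions on this map are not known here.

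The gene rsaA encodes the surface-layer protein, one of the most abundant proteins of the cell, and was deleted from its own place and inserted at the van or the xyl locus to ask whether it creates a boundary. The empty plasmid was inserted at van, and no strain had an empty insertion at xyl. For rsaA at xyl, the effect of rsaA thus cannot be told apart from that of an insertion. Each relocation strain had a position with far fewer contacts across it than the strain with the empty plasmid. With rsaA at van this was the bin from 2620001 to 2630000, with an insulation score of -1.63 against -0.11 with the empty plasmid and 0.25 and 0.26 in the wild-type replicates. With rsaA at xyl it was the bin from 940001 to 950000, with -1.99 against -0.16 with the empty plasmid and 0.01 and -0.03 in the replicates. The differences from the empty plasmid were -1.52 and -1.82, with counting SDs of 0.0221 and 0.0517, while the largest fall between any pair among the empty-plasmid strain and the 3 untreated libraries was -0.80. At its own position the van and xyl strains stood among the lowest 0.494% and 0.247% of all bins, and the other relocation strain was near the median bin (0.13 at the van position, 0.11 at the xyl position). More than 100 kb away, the lowest difference from the empty plasmid was -0.96 with rsaA at van and -0.18 with rsaA at xyl. These bins were chosen after their values were seen, as the largest loss in each strain, and were not taken from an annotation.

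**Figure D3:**
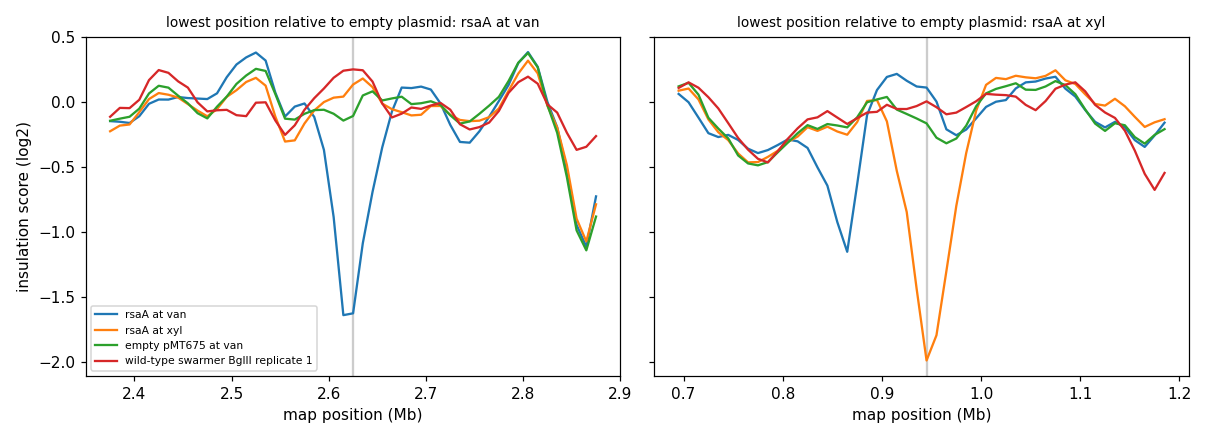
Insulation score (log2) against map position (Mb) around the bin of largest loss in rsaA at van (left) and rsaA at xyl (right), 1 line per library. The score reached -1.63 at 2.625 Mb in rsaA at van and -1.99 at 0.945 Mb in rsaA at xyl, while the empty-plasmid strain was at -0.11 and -0.16.

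Read depth in genomic DNA was higher near coordinate 0 than at the opposite point at every time, most at 45 min. The ratio of median depth within 200 kb of coordinate 0 to that within 200 kb of the opposite point was 1.03 at 0 min (95% bootstrap interval over windows 1.02 to 1.04), 1.38 at 10 min (1.34 to 1.42), 1.66 at 30 min (1.61 to 1.69), 1.92 at 45 min (1.86 to 1.96), 1.63 at 60 min (1.59 to 1.68) and 1.17 at 75 min (1.15 to 1.20). Depth 1 Mb from coordinate 0 relative to the terminus was 0.94 and 0.90 on the right and left arms at 10 min, 1.15 and 1.06 at 30 min and 1.59 and 1.45 at 45 min, and at 1.5 Mb it was 1.07 and 1.10 at 45 min and 1.37 and 1.40 at 60 min. The ratio rose and came down again, a course that a linear measure can miss. Over the 6 times no linear relation of the ratio with time was detected (r = 0.28, exact permutation p = 0.585; rho = 0.257, exact permutation p = 0.658; r = 0.641 without 0 and 75 min). Intervals cover variation between windows only, with 1 library per time, and row totals of the Hi-C maps gave a ratio below 1 at 75 min (0.982).

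Over the same 6 times the inter-arm contacts of the terminus-proximal part were 2.40, 2.39, 2.06, 2.09, 2.06 and 2.04 from 0 to 75 min, and those of the origin-proximal part 3.08, 3.34, 3.13, 3.27, 3.59 and 3.51. The terminus-proximal part had the strongest linear relation with time over all 6 times (r = -0.872, exact permutation p = 0.0167, adjusted p = 0.100 over 6 measures). Without 0 and 75 min, that of the share at 20 to 200 kb was stronger (r = -0.835 against -0.813). The terminus-proximal part had a rho of -0.829 (exact permutation p = 0.0583, adjusted p = 0.263). It did not pass the correction, nor did the origin-proximal part (r = 0.778, exact permutation p = 0.0764; rho = 0.771, exact permutation p = 0.103; r = 0.554 without those times), median boundary depth (r = -0.782, exact permutation p = 0.0750; rho = -0.657, exact permutation p = 0.175; r = -0.767), the share at 20 to 200 kb (r = -0.464, exact permutation p = 0.393; rho = -0.657, exact permutation p = 0.175; r = -0.835) or all inter-arm contacts (r = 0.038, exact permutation p = 0.946; rho = 0.0857, exact permutation p = 0.919; r = -0.097). With 100 kb bands and windows, r was -0.336 for boundary depth and -0.113 for all inter-arm contacts. Adjusted p was 0.153 for the origin-proximal part and for boundary depth, 0.590 for the share and 0.946 for all inter-arm contacts. Contacts per library declined from 6652977 at 0 min to 1857223 at 60 min and were 3110936 at 75 min.

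**Figure D4:**
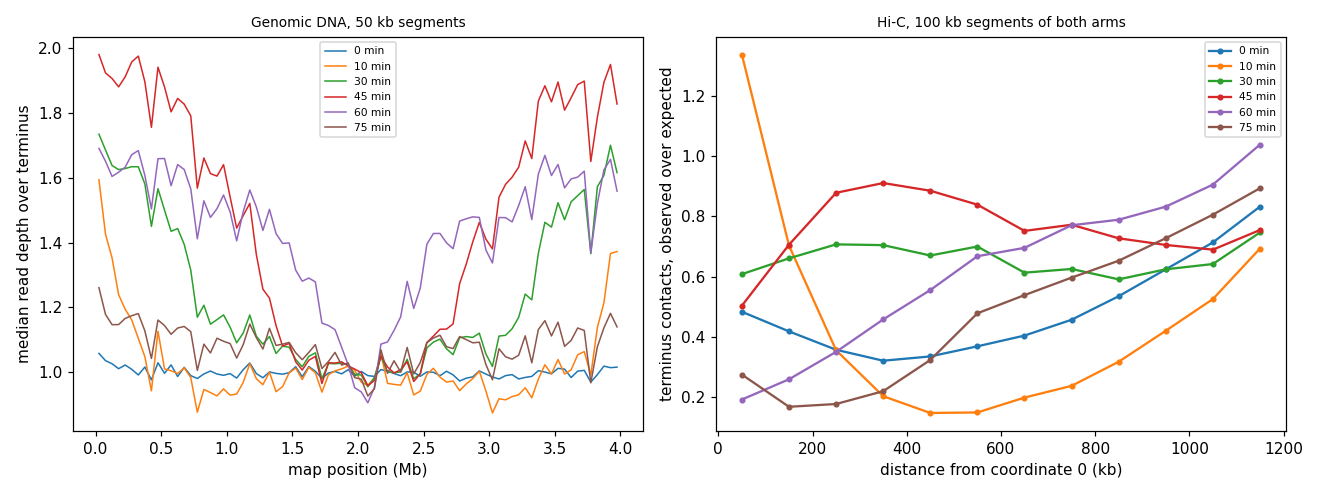
Median genomic DNA depth in 50 kb segments over the terminus against map position (Mb, left), and Hi-C contacts of 100 kb segments with the terminus region, observed over expected, against distance from coordinate 0 (kb, right), 1 line per time. The origin to terminus ratio of depth was highest at 45 min (1.92), and the segment within 100 kb of coordinate 0 had its highest contact with the terminus region at 10 min (1.34).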

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

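All tests in this part were chosen after the pattern was seen. In genomic DNA, 71 windows at 0 min had over 2 times the depth of their neighbours, against 0 windows at each of the later times, and they lie in data that the origin and terminus comparison leaves mostly unused. They held 7.92% of the reads at 0 min and 1.70% to 1.88% later, and the highest, from 478001 to 479000, reached 5035 RPM. Counting noise of a shallower library is argued against, since the 5 later libraries thinned to the 0 min total had 0 such windows, taking the smallest step between RPM values (0.161 at 0 min) as 1 read. Hi-C row totals did not show extra copies in the cells. The 51 bins that hold the windows had a median log2 excess of 0.0300 at 0 min over 10 min, against 0.29 in genomic DNA. Row totals count contacts at cut sites in 10 kb bins, so copies of a 1 kb stretch without such a site could be missed. Nor do the labels say that both kinds of library came from the same cells, so extra copies stay open. DNA added during preparation of the 0 min genomic DNA library was not tested, and no other biological explanation was tested.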

How the results depend on the processing

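Of the alternatives, 70 moved their value by less than the tolerance used for it or stayed on the same side of the threshold, 38 moved it further and 1 reversed. Boundary counts were taken as alike within 1.5 times of each other. For other values the spread was the SD of 3 untreated libraries, or the bootstrap interval for read depth. Alternatives named as added were chosen after seeing the data. The cause of these changes was not tested. Boundary counts ranged from 19 to 29, with 26 to 28 when 1 replicate was left out. Keeping 10 kb pairs (added) gave a wild-type share of 43.7%, and the best axis an inter-arm ratio of 3.29. Boundary depth differences with a 100 kb window were -0.16 (novobiocin 25), -0.19 (novobiocin 50) and -0.17 (rifampicin). Novobiocin 25 gave -0.20 after thinning and -0.31 at boundaries of the 0 min library (added). Novobiocin 50 gave -0.43 to -0.32 without one replicate and -0.32 against 3 untreated libraries (added). Rifampicin gave -0.27 to -0.21 without one replicate and, against the 30 min library, -0.16 and a share ratio of 0.942. The smc inter-arm ratio was 0.626 of wild type on each library's best axis (added). For rsaA at van and at xyl the differences were -1.55 and -1.89 with a 30 kb window, -1.27 and -1.70 with 100 kb, -1.88 and -1.98 against wild type, and -1.76 and -2.10 against the other strain (added). Read depth ratios with 100 kb windows were 1.05, 1.53, 1.72, 1.75 and 1.24 at 0, 10, 30, 60 and 75 min, and with 400 kb 1.02, 1.21, 1.59, 1.48 and 1.13. The mean gave 1.00 at 0 min. Hi-C row totals gave 1.05, 1.11, 1.38, 1.60, 1.35 and, below 1, 0.982 from 0 to 75 min. Gene list alternatives were not run, since no gene was placed. No paired analysis was possible because only 1 group has over 1 replicate.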

Other observations

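In this part every test but that of sequencing depth was chosen after its result was seen. Contacts between origin-proximal DNA and the terminus region, within 400 kb of the point opposite coordinate 0, changed over the cell cycle. The segments within 100 kb of coordinate 0 had observed over expected contacts with that region of 0.48 at 0 min, 1.34 at 10 min, 0.61 at 30 min, 0.50 at 45 min, 0.19 at 60 min and 0.28 at 75 min. Segments 300 to 400 kb away had 0.32, 0.20, 0.70, 0.91, 0.46 and 0.22 at these times. The highest gain over 0 min was thus within 100 kb at 10 min (2.76 times), at 300 to 400 kb at 30 and 45 min (2.19 and 2.83 times) and at 500 to 600 kb at 60 min (1.81 times). Each time was 1 library.

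Both wild-type replicates had fewer contacts across the bins centred on 1.505, 1.175 and 2.515 Mb than every other BglII library, including the untreated 0 min library of the time course. At 1.505 Mb the scores were -0.33 and -0.39 against -0.07 at 0 min, and over the 3 positions the replicates were on average -0.35 from the 0 min library. Thinning all libraries to one depth kept 111.4% of this difference and the maps before normalization held 97.9% of it, which argues against depth and the deposited normalization. A difference in cultures or preparation may remain, and was not tested since the labels give no batch. The wild-type reference for drugs and mutants holds these 2 libraries.

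The NcoI library and the strain with rsaA at van shared low scores near 0.865 Mb (-0.77 and -1.15) and 1.575 Mb (-0.56 and -0.52), where the 0 min library had -0.30 and -0.02. The title of the rsaA at van library names no enzyme, unlike those of the other Hi-C libraries. The strain's row totals correlated at 0.0207 with the NcoI library and at 0.913 or more with the libraries labelled BglII, which argues against a library cut with NcoI. At 0.865 Mb the strain lay -0.38 from the NcoI library (counting SD 0.0408). The largest fall at any bin between untreated libraries reached -0.49 (replicate 2 against 0 min), so this bin does not decide on a mixture. At 1.575 Mb a mixture would have to be almost all NcoI, which the row totals argue against. The maps before normalization held 108.2% of the strain's mean difference from the 0 min library at these positions, which argues against the deposited normalization. A shared feature of the strain or culture may remain and was not tested.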
